A study of Saccharomyces cerevisiae with 32 samples.

How the data were processed

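Poly-A RNA of Saccharomyces cerevisiae was sequenced in 32 libraries, 1 for each of 2 strains, 2 sugars and 8 times from 0 to 120 min. Per the labels' protocols, cells grew to log phase in yeast nitrogen base with 2% galactose, glucose or fructose was added to 2%, RNA was extracted with hot acidic phenol, and stranded libraries were made from poly-A RNA. Per the submitters' processing notes, reads were called with CASAVA 1.4, aligned with TopHat2 to the sacCer3 genome and summarised with Cuffnorm. The deposited table holds FPKM, the unit the authors' file name gives, for 6717 genes in 32 columns, and all 32 columns were matched to the labels. How Cuffnorm scaled the libraries, and whether strand was used in counting, is not given in the sources used here. Fragment counts and raw reads were not analysed here.

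Of the 6717 gene IDs 6025 were matched to the reference annotation and 692 were not. An entry without a gene ID was left out of every test. Depth was estimated per library from the step between low FPKM values times gene length less an offset. Step and offset were fitted on genes of 900 to 8000 bp with up to 8 fragments, and fragments were summed over genes of at least 400 bp. Of 1315 such low values 88.6% lay within 0.1 of a whole number of fragments (74.2% in the lowest library). This share describes the fit and is not a separate check, since the step was chosen on the same values. The estimates ran from 3.88 to 9.76 M fragments (M, the SI prefix mega) (median 7.6), and 1 fragment over 1 kb equalled 0.0876 to 0.3326 FPKM. Gene lengths were coding lengths from the annotation.

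Values were log2(FPKM + 1), and 6203 genes with a mean of at least 1 FPKM over all libraries were tested. Of these, 681 were under 300 bp or unmatched. Tests used limma 3.58.1 in R 4.3.3 with a trended prior variance and Benjamini-Hochberg adjustment within each comparison, and a gene was called at an adjusted p under 0.05 and at least 2-fold. Galactose libraries were compared between strains (2 against 2). Each course was compared with both galactose libraries of its strain in a cell-means fit of all 32 libraries. Strain differences, and whether these depended on the sugar, came from a fit of 16 tps1 minus WT differences at matched times, and sugar differences from 16 glucose minus fructose differences. Early times were 3, 5, 10 and 15 min and late times 30, 60 and 120 min. Serial samples of a course were treated as independent in these fits.

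For groups of genes, 30 lists were fixed from general knowledge of yeast pathways and tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry as alternatives, adjusted over the lists of a comparison. The mitochondrially encoded list had 2 measured genes and was not tested, and AAD16 of the oxidative stress list was not matched. Named genes followed a rule: TPS1 first, then in each comparison the 6 highest and 6 lowest called genes that went the same way at every time, up to 4 called members with the largest difference from each list that passed its test, and 30 fixed genes. These choices, the comparisons and most alternatives were fixed before the data were examined.

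Alternatives were pseudocounts of 0.1 and 5, no filter, median-of-ratios scaling, no trend, a single galactose library as baseline, no matching by time, strain differences relative to galactose, and each time or library left out in turn. Equal FPKM sums, leaving out genes under 300 bp or unmatched, and the other course's galactose library as baseline were chosen after seeing the data. The equal sums were taken over matched genes of at least 300 bp. Label swaps at matched times were counted over 64 splits. The pipeline was tested on simulated data with 200 of 6203 genes changed, for part of the comparisons. It recovered 82 to 97% of changes of 1.5 (log2) and 96 to 100% of changes of 3, with 1 to 5 false calls per comparison. These figures test the code and do not measure power or false calls in the real libraries with their serial samples. Tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, and scipy 1.17.1, with the R package data.table (1.17.8), and figures with matplotlib 3.10.9.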

Results

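Messenger RNA was sequenced from budding yeast of a wild-type strain (WT, DBY12000) and of a tps1 mutant strain (tps1, DBY12383). TPS1 encodes trehalose-6-phosphate synthase, the enzyme that makes the precursor of trehalose, and cells without it are known to grow on galactose but poorly on glucose or fructose. Each strain grew in 2% galactose, was sampled at 0 min, received glucose or fructose to 2%, and was sampled again after 3, 5, 10, 15, 30, 60 and 120 min. This gave 32 libraries, 16 per strain, in 4 courses of 8 times with 1 library per strain, sugar and time. The 2 libraries of a strain taken at 0 min, both still in galactose, were its baseline (n = 2). Whether these were separate cultures is not given in the sources used here, and the description of the tps1 fructose library at 0 min carries an unexplained mark (trd). The times from 3 to 15 min were the early phase (n = 4 per course) and those from 30 to 120 min the late phase (n = 3 per course). No time after addition had a replicate culture, so p-values after addition describe serial samples of 1 culture per course and not the variation between cultures. Those in galactose describe 2 libraries per strain. Values are given as FPKM (by name, fragments per kilobase and M fragments, M standing for the SI prefix mega) for 6717 genes. Of these, 6203 with a mean of at least 1 FPKM were tested with limma. A gene was called when its adjusted p was under 0.05 and it differed at least 2-fold, levels are given as mean ± SD, and log2 differences as estimate ± SE.

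The files gave no fragment counts, and depth was estimated from the spacing of low FPKM values. That spacing was fitted to these values, and 88.6% of them then lay within 0.1 of a whole number of fragments. In the WT glucose course the estimates were 7.82, 7.56, 7.39, 7.21, 7.64, 7.5, 7.49 and 6.04 M fragments from 0 to 120 min. In the WT fructose course they were 8.97, 6.74, 8.99, 4.25, 7.93, 9.76, 8.39 and 7.45 M. In the tps1 glucose course they were 7.63, 7.8, 7.71, 7.84, 8.11, 7.58, 6.16 and 5.8 M, and in the tps1 fructose course 7.26, 7.76, 7.97, 6.56, 7.74, 7.87, 3.88 and 5.46 M. Estimated depth at 30 min of glucose was similar in WT and tps1 (7.5 and 7.58 M). Yet 1 fragment over 1 kb equalled 0.1243 FPKM in WT and 0.1757 FPKM in tps1. The FPKM values thus did not follow estimated depth alone, and the authors' scaling can account for part of the sums given next. The sum of all FPKM values was higher after sugar in the tps1 courses, from 1.19 and 1.3 M in galactose to between 1.51 and 2.58 M after sugar (2.42, 2.28 and 2.09 M at 30, 60 and 120 min of glucose), against 1.32 to 1.6 M in WT after sugar. As deposited, the median gene lay between -0.05 and 0.02 on the log2 scale in all 19 comparisons. Libraries were also scaled to equal FPKM sums over matched genes of at least 300 bp. That moved the median gene to -0.76 and -0.87 in late tps1 glucose and fructose, and to -0.49 and -0.46 in early tps1. It then lay between -0.14 and -0.28 in WT, and between -0.21 and -0.54 in the differences between strains after sugar (0.06 in galactose). All changes below are therefore relative to the median gene. Genes of near-identical sequence (the HXT transporters, the MAL genes, TDH1 to TDH3, ENO1 and ENO2, and paired ribosomal protein genes) could share reads, and the sources used here do not say whether counting used the strand, so their split is uncertain.

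TPS1 (YBR126C, chromosome II, 488905 to 490392, reverse strand, sacCer3) separated the strains in every library. It lay between 43.2 and 325.7 FPKM in the 16 WT libraries and between 0 and 1.18 FPKM in the 16 tps1 libraries, where it was listed at 0 in glucose at 30 min and in fructose at 10 min. In galactose its level was 302.1 ± 33.4 FPKM in WT (n = 2) and 0.196 ± 0.0566 FPKM in tps1 (n = 2). That difference was -7.98 ± 0.13 on the log2 scale (adjusted p = 0.000792). After sugar the difference was -6.67 ± 0.31 and -7.06 ± 0.35 in early and late glucose, and -7.01 ± 0.31 and -7.17 ± 0.35 in early and late fructose. Relative to the difference already present in galactose, TPS1 gave 1.31, 0.92, 0.98 and 0.81 in the same order, values that turn the direction because the WT level fell from its galactose level and the tps1 level had nowhere to fall.

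In galactose, before any sugar was added, 8 of 6203 genes differed between the strains, 1 higher and 7 lower in tps1. TPS1 was the only named call that stood when any of the 4 libraries was left out. RGI2, a respiratory growth gene, was higher in tps1 (22.8 ± 4.45 against 2.94 ± 0.188 FPKM, log2 difference 2.59 ± 0.17, adjusted p = 0.0475, and 0.248 without the WT glucose 0 min library). YRO2, a plasma membrane protein gene, was lower (10.7 ± 0.25 against 53.8 ± 0.242 FPKM, log2 difference -2.23 ± 0.09, adjusted p = 0.0104), as were the short genes YFL041W-A and YHR213W-A and the genes YHR032C-A and YOL083C-A, which had no match in the annotation. The 34 measured general stress genes had a median difference of -0.50 and the 20 iron regulon genes one of -0.47, with 0 of each called (limma, 729 of all genes at an unadjusted p under 0.05). Adjusted over the list alone, 5 stress genes and 4 iron genes were lower. Camera gave those lists adjusted p-values of 2.34e-15 and 2.41e-08, and both had an adjusted p = 0.69 with an estimated correlation. The count of 8 was 3 without either tps1 library, without the filter on low values, or with the spread taken from the 16 matched differences, and 37 (7 higher, 30 lower) without genes under 300 bp or unmatched.

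**Figure D1:**
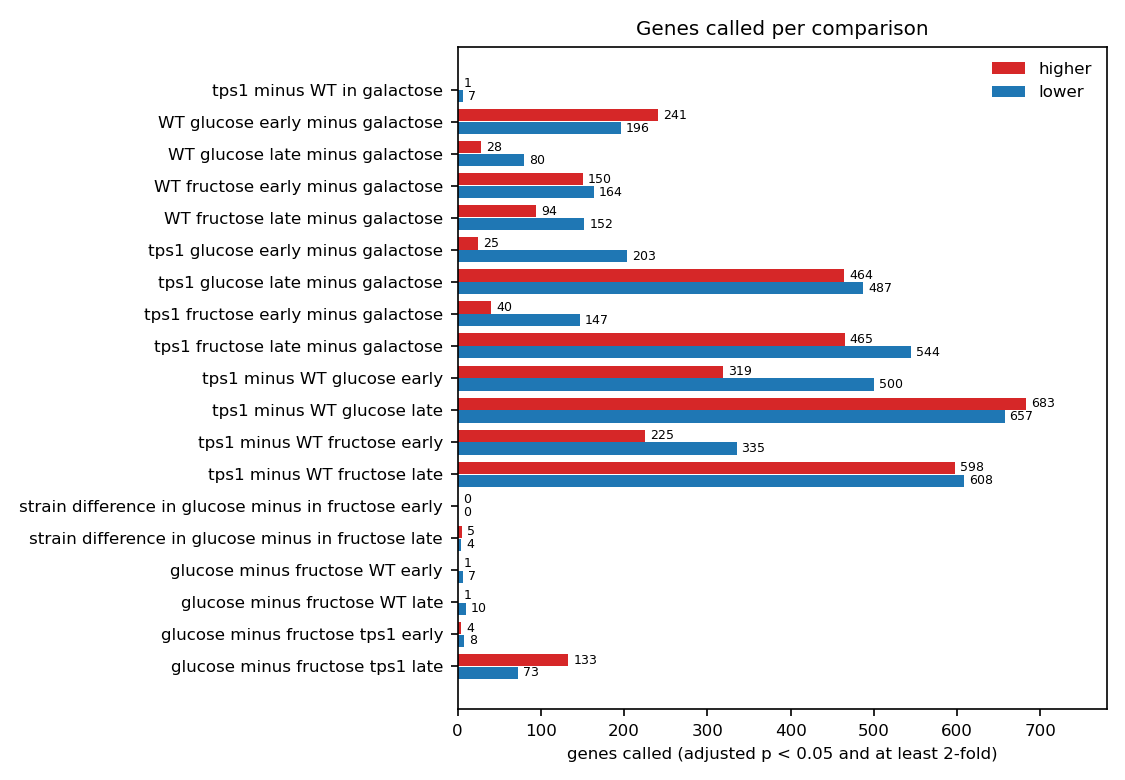
Bars give the number of genes called in each comparison (horizontal axis, genes with an adjusted p under 0.05 and at least 2-fold), red for higher and blue for lower, of 6203 tested. Late tps1 minus WT in glucose has the longest bars (683 higher, 657 lower), and the split of the tps1 bars depends on scaling, since equal FPKM sums give 71 higher and 2190 lower for late tps1 glucose in place of 464 and 487.

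Glucose addition to WT cells moved 437 genes in the early phase, 241 up and 196 down against galactose. The rise was led by FMP48, a mitochondrial protein kinase gene, from 6.68 ± 0.53 to 188.7 ± 119.3 FPKM (log2 4.42 ± 0.44, adjusted p = 5.85e-07). TPO2, a polyamine exporter gene, rose from 14.4 ± 0.369 to 287.2 ± 151.1 FPKM (4.05 ± 0.41, adjusted p = 5.85e-07). Genes for making ribosomes rose as a group, 28 of 43 measured (camera adjusted p = 7.6e-23, and adjusted p = 0.328 with an estimated correlation), among them the nucleolar gene NSR1 (1.71 ± 0.32) and SSF1 (1.49 ± 0.25). Genes for using other sugars fell, with 6 of 9 in the galactose regulon (9.12e-08, and adjusted p = 0.253 with an estimated correlation), led by the galactose permease gene GAL2 (-3.99 ± 0.64) and the glucose sensing regulator MTH1 (-2.95 ± 0.52). Of the 8 disaccharide genes 7 fell (5.48e-08, and adjusted p = 0.103 with an estimated correlation), including the maltose transporter genes MAL31 (-2.81 ± 0.35) and MAL11 (-2.43 ± 0.37). The falls also took in 6 of 9 trehalose genes (2.39e-06, and adjusted p = 0.328 with an estimated correlation), such as the acid trehalase ATH1 (-1.76 ± 0.31). Of 10 glycogen genes 6 fell (5.13e-07, and adjusted p = 0.328 with an estimated correlation), such as the glycogenin GLG1 (-2.41 ± 0.40). In addition, 8 of 15 tricarboxylic acid cycle genes fell (1e-07, and adjusted p = 0.433 with an estimated correlation). So did 11 of 34 general stress genes (4.52e-08, and adjusted p = 0.433 with an estimated correlation) and 7 of 15 genes of gluconeogenesis and the glyoxylate cycle (4.92e-05, and adjusted p = 0.433 with an estimated correlation). Adjusted over the list alone, the counts were 28, 6, 7, 6, 7, 11, 17 and 7 in the order given. TMA10, a ribosome-associated protein gene on the general stress list, fell by 6.52 ± 0.91. Outside these lists, RGI1, a respiratory growth gene, fell by 5.38 ± 0.67. With a single galactose library as baseline the 437 calls became 227 (same course) or 77 (other course), and without 10 min they were 261. Equal FPKM sums gave 405 calls, 154 higher and 251 lower.

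By the late phase in glucose, 108 genes stood apart from galactose in WT, 28 higher and 80 lower. Hexose transporter genes now led the rise, with 6 of 15 transport and sensing genes higher and 2 lower (camera adjusted p = 0.00891, and adjusted p = 0.351 with an estimated correlation). HXT3, a low-affinity glucose transporter gene, went from 10.2 ± 1.36 to 401.9 ± 177.4 FPKM (5.05 ± 0.82, adjusted p = 0.00071). HXT1, the transporter gene best known for induction by high glucose, went from 5.4 ± 0.735 to 433.7 ± 63.2 FPKM (6.08 ± 1.27, adjusted p = 0.0072, and 0.0929 or 0.138 with either galactose library alone as baseline). ARI1, an aldehyde reductase gene, rose by 4.76 ± 0.69, and STD1, a glucose sensing regulator, by 2.69 ± 0.43. Of the 9 galactose regulon genes 6 were lower (3.49e-15, and adjusted p = 0.0353 with an estimated correlation), including GAL10 (-2.18 ± 0.35) and GCY1 (-2.81 ± 0.38), though GAL10 overlaps an antisense noncoding RNA gene along 1548 bp. Gluconeogenesis and glyoxylate genes fell in 5 of 15 cases (9.52e-08, and adjusted p = 0.189 with an estimated correlation), among them the cytosolic isocitrate dehydrogenase IDP2 (-2.04 ± 0.36). Just 2 of 15 tricarboxylic acid cycle genes fell (7.83e-11, and adjusted p = 0.189 with an estimated correlation). Adjusted over the list alone, 7 transport and sensing genes were higher and 3 lower, and 7, 6 and 11 genes of the other lists were lower. DSF1, a putative mannitol dehydrogenase gene, fell by 4.09 ± 0.56. The 108 calls became 23 or 28 with the same or the other course's galactose library alone, and 61 without 30 min, while equal FPKM sums gave 155 (20 higher, 135 lower).

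Fructose moved 314 genes in WT in the early phase, 150 up and 164 down. FMP48 (4.77 ± 0.44, adjusted p = 1.68e-07) and TPO2 (4.53 ± 0.41, adjusted p = 1.65e-07) again led the rise, with YRO2 next (from 53.8 ± 0.242 to 792.9 ± 350.8 FPKM, 3.72 ± 0.56). Ribosome biogenesis genes rose in 13 of 43 cases (camera adjusted p = 1.73e-17, and adjusted p = 0.397 with an estimated correlation), a count that was 1 with equal FPKM sums. TMA10 (-5.94 ± 0.91), RGI1 (-5.52 ± 0.67), GAL2 (-3.60 ± 0.64) and MTH1 (-2.86 ± 0.52) fell, and so did the invertase gene SUC2, from 121.6 ± 8.43 to 35.1 ± 17.6 FPKM (-1.87 ± 0.33, adjusted p = 0.000771). Disaccharide genes fell in 7 of 8 cases (8.35e-09, and adjusted p = 0.0638 with an estimated correlation), including MAL31 (-2.99 ± 0.35). Glycogen genes fell in 7 of 10 (4.31e-07, and adjusted p = 0.397 with an estimated correlation), including GAC1 (-2.94 ± 0.49), a phosphatase subunit gene. Galactose regulon genes fell in 4 of 9 cases (2.31e-06, and adjusted p = 0.397 with an estimated correlation), tricarboxylic acid cycle genes in 5 of 15 (2.91e-06, and adjusted p = 0.402 with an estimated correlation). With adjustment over the list alone, the counts were 13, 7, 8, 5 and 9. The 314 calls became 66 or 76 with the same or the other course's galactose library alone, 185 without 10 min and 529 without 3 min, and equal FPKM sums gave 310 (64 higher, 246 lower).

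In the late fructose phase 246 genes differed from galactose in WT, 94 higher and 152 lower. Ribosomal protein genes rose in 24 of 138 cases (camera adjusted p = 5.16e-41, and adjusted p = 0.215 with an estimated correlation), a count of 5 with equal FPKM sums. Genes for the mitochondrial counterpart fell in 5 of 56 cases (1.77e-20, and adjusted p = 0.215 with an estimated correlation), and tricarboxylic acid cycle genes in 8 of 15 (1.73e-09, and adjusted p = 0.215 with an estimated correlation). HXT3 (4.41 ± 0.82, from 10.2 ± 1.36 to 293.0 ± 209.3 FPKM, adjusted p = 0.00319) and HXT1 (5.28 ± 1.27, to 249.9 ± 40.7 FPKM, adjusted p = 0.0118) were again among the rises. Their adjusted p-values were 0.0546 or 0.0612 for HXT3 and 0.14 or 0.0983 for HXT1 with the same or the other course's galactose library alone. ARI1 rose by 4.47 ± 0.69 and DSF1 fell by 4.39 ± 0.56. Of the galactose regulon 6 of 9 genes fell (7.77e-08, and adjusted p = 0.215 with an estimated correlation). When adjusted over the list alone, 24, 5, 13 and 7 genes of these lists were called. The 246 calls became 20 or 17 with the same or the other course's galactose library alone, 94 without 30 min, 126 without 60 min and 461 without 120 min. Equal FPKM sums gave 449 calls, 45 higher and 404 lower.

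In tps1, the early response to glucose held 228 genes, and 203 of them fell. Cell cycle genes were prominent among the falls. The mitotic cyclin gene CLB2 went from 35.0 ± 3.94 to 9.37 ± 2.64 FPKM (-1.82 ± 0.26, adjusted p = 0.000113). The G1 cyclin genes CLN1 and CLN3 fell by 2.21 ± 0.32 and 1.79 ± 0.29, the cyclin gene PCL1 by 2.49 ± 0.39, and SCW11, which acts at cell separation, by 1.90 ± 0.29. Of the 18 genes of the G2 to M and M to G1 periods 6 fell (camera adjusted p = 3.28e-07, and adjusted p = 0.484 with an estimated correlation). Of 25 G1 and S phase genes 4 fell (0.0269, and adjusted p = 0.484 with an estimated correlation). MIG1, the repressor of genes for other carbon sources, went from 54.4 ± 5.57 to 9.29 ± 2.39 FPKM (-2.45 ± 0.35, adjusted p = 0.000113), and ILV5, for branched-chain amino acids, fell by 2.13 ± 0.42. Glycolysis and fermentation genes rose in 3 of 23 cases (0.00113, and adjusted p = 0.484 with an estimated correlation) and ribosomal protein genes in 4 of 138 (2.31e-23, and adjusted p = 0.484 with an estimated correlation), counts that were 0 for both with equal FPKM sums. With adjustment over the list alone, the counts of these lists were the same, 6, 4, 3 and 4. The galactose regulon of WT's response had 0 of 9 genes called here (limma). The 228 calls became 138 or 105 with the same or the other course's galactose library alone, 127 without 15 min, 147 without 10 min, 364 without 3 min and 136 with a pseudocount of 5. Equal FPKM sums gave 905 calls, 3 higher and 902 lower.

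Late in glucose, 951 genes differed from galactose in tps1, 464 higher and 487 lower. Glycolytic genes were higher in 12 of 23 cases (camera adjusted p = 0.0011, and adjusted p = 0.534 with an estimated correlation), among them TDH1 (2.74 ± 0.45), GPM1 (2.44 ± 0.32) and TDH3, which went from 14568.5 ± 138.5 to 63100.2 ± 18110.3 FPKM (2.07 ± 0.26, adjusted p = 1.58e-06). With equal FPKM sums 6 glycolytic genes were higher and 3 lower. General stress genes rose in 11 of 34 cases (0.0011, and adjusted p = 0.961 with an estimated correlation), with a median of 0.96 that became 0.19 with equal FPKM sums, where 4 were higher and 1 lower. The small heat shock protein gene HSP26 was at 62.6, 163.9 and 488.5 FPKM at 30, 60 and 120 min against 15.5 ± 5.25 FPKM in galactose (3.42 ± 0.70, adjusted p = 0.000375). GRE1, for a stress-induced hydrophilin, rose by 2.54 ± 0.33, and SPI1, for a cell wall protein, by 2.05 ± 0.25. Ribosomal protein genes were higher in 42 of 138 cases and lower in 1 (1.05e-11, and adjusted p = 0.961 with an estimated correlation), with a median change of 0.63 that became -0.15 with equal FPKM sums. Their median was 0.96, 0.76 and 0.13 at 30, 60 and 120 min, and that of glycolytic genes 1.44, 1.27 and 0.63. RPL3 went from 2927.3 ± 197.8 to 13164.7 ± 3112.7 FPKM (2.14 ± 0.25). Oxidative stress genes rose in 6 of 20 cases (0.0235, and adjusted p = 0.534 with an estimated correlation), with a median of 0.54 that became -0.20 with equal FPKM sums. Mitochondrial ribosomal protein genes fell in 24 of 56 cases (2.1e-11, and adjusted p = 0.641 with an estimated correlation), among them MRPS8 (-1.73 ± 0.35). Of the cell cycle genes, 7 of 18 G2 to M and M to G1 genes fell (0.00182, and adjusted p = 0.641 with an estimated correlation), among them CLB2 (-1.96 ± 0.27) and SWI5 (-1.61 ± 0.24). The ammonium permease gene MEP2 fell by 2.43 ± 0.30. When adjusted over the list alone, the counts were 13, 11, 42 and 1, 6, 24 and 7. GAL10 stood at 14250.4 ± 2962.8 FPKM against 5340.9 ± 693.2 FPKM in galactose (1.4 ± 0.35, adjusted p = 0.00214), a call lost with equal FPKM sums (0.63, adjusted p = 0.112). Under that scaling 2261 genes were called, 71 higher and 2190 lower.

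Fructose called 187 genes in early tps1, 40 higher and 147 lower. The genes that fell included MSA1, a regulator of G1 genes (-2.27 ± 0.30, adjusted p = 5.51e-05), YIA6, a mitochondrial NAD transporter gene (-2.14 ± 0.35), and CLB2 (-1.47 ± 0.26, to 12.1 ± 2.12 FPKM). Of the cell cycle genes, 5 of 18 G2 to M and M to G1 genes fell (camera adjusted p = 0.000166, and adjusted p = 0.65 with an estimated correlation). Glycolytic genes rose in 5 of 23 cases (0.00245, and adjusted p = 0.65 with an estimated correlation) and ribosomal protein genes in 6 of 138 (5.47e-24, and adjusted p = 0.65 with an estimated correlation), with 0 of each higher under equal FPKM sums. Hexose transport and sensing genes fell in 3 of 15 cases (0.0181, and adjusted p = 0.65 with an estimated correlation). With adjustment over the list alone, the counts were the same, 5, 5, 6 and 3. The 187 calls became 30 with the same course's galactose library alone, 122 without 15 min, 304 without 3 min and 116 with a pseudocount of 5, and equal FPKM sums gave 694 (5 higher, 689 lower).

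Late in fructose, 1009 genes differed from galactose in tps1, 465 higher and 544 lower. Ribosomal protein genes rose in 62 of 138 cases (camera adjusted p = 3e-23, and adjusted p = 0.719 with an estimated correlation), with a median change of 0.97 that was 0.06 with equal FPKM sums. RPS25A (2.14 ± 0.28) and RPL43B (2.03 ± 0.31) were among them. Glycolytic genes were higher in 11 of 23 cases and lower in 1 (0.00107, and adjusted p = 0.719 with an estimated correlation), among them ENO2 (2.09 ± 0.37), TPI1 (2.04 ± 0.31) and TDH3 (2.02 ± 0.26). PFK27, whose product makes the glycolysis activator fructose-2,6-bisphosphate, fell by 1.60 ± 0.28. ADH2, an alcohol dehydrogenase that glucose normally represses, went from 89.5 ± 52.3 to 450.4 ± 99.7 FPKM (2.43 ± 0.30, adjusted p = 3.09e-06). Oxidative stress genes rose in 7 of 20 cases (0.0123, and adjusted p = 0.719 with an estimated correlation), including the thioredoxin gene TRX2 (1.92 ± 0.24), but their median of 0.78 became -0.08 with equal FPKM sums. Targets of Gcn4 in amino acid synthesis were higher in 9 of 30 cases and lower in 1 (0.00105, and adjusted p = 0.73 with an estimated correlation), with a median of 0.50 that became -0.41 with equal FPKM sums. ILV5 fell by 2.75 ± 0.44. Purine synthesis and salvage genes rose in 6 of 23 cases (0.00107, and adjusted p = 0.73 with an estimated correlation), with a median of 0.72 that became -0.19. Of the G2 to M and M to G1 genes 9 of 18 fell (0.00108, and adjusted p = 0.719 with an estimated correlation), among them CLB2 (-2.06 ± 0.27). When adjusted over the list alone, the counts were 63, 11 and 1, 7, 9 and 1, 6, and 9. Scaled to equal FPKM sums, the libraries gave 2566 calls, 22 higher and 2544 lower.

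**Figure D2:**
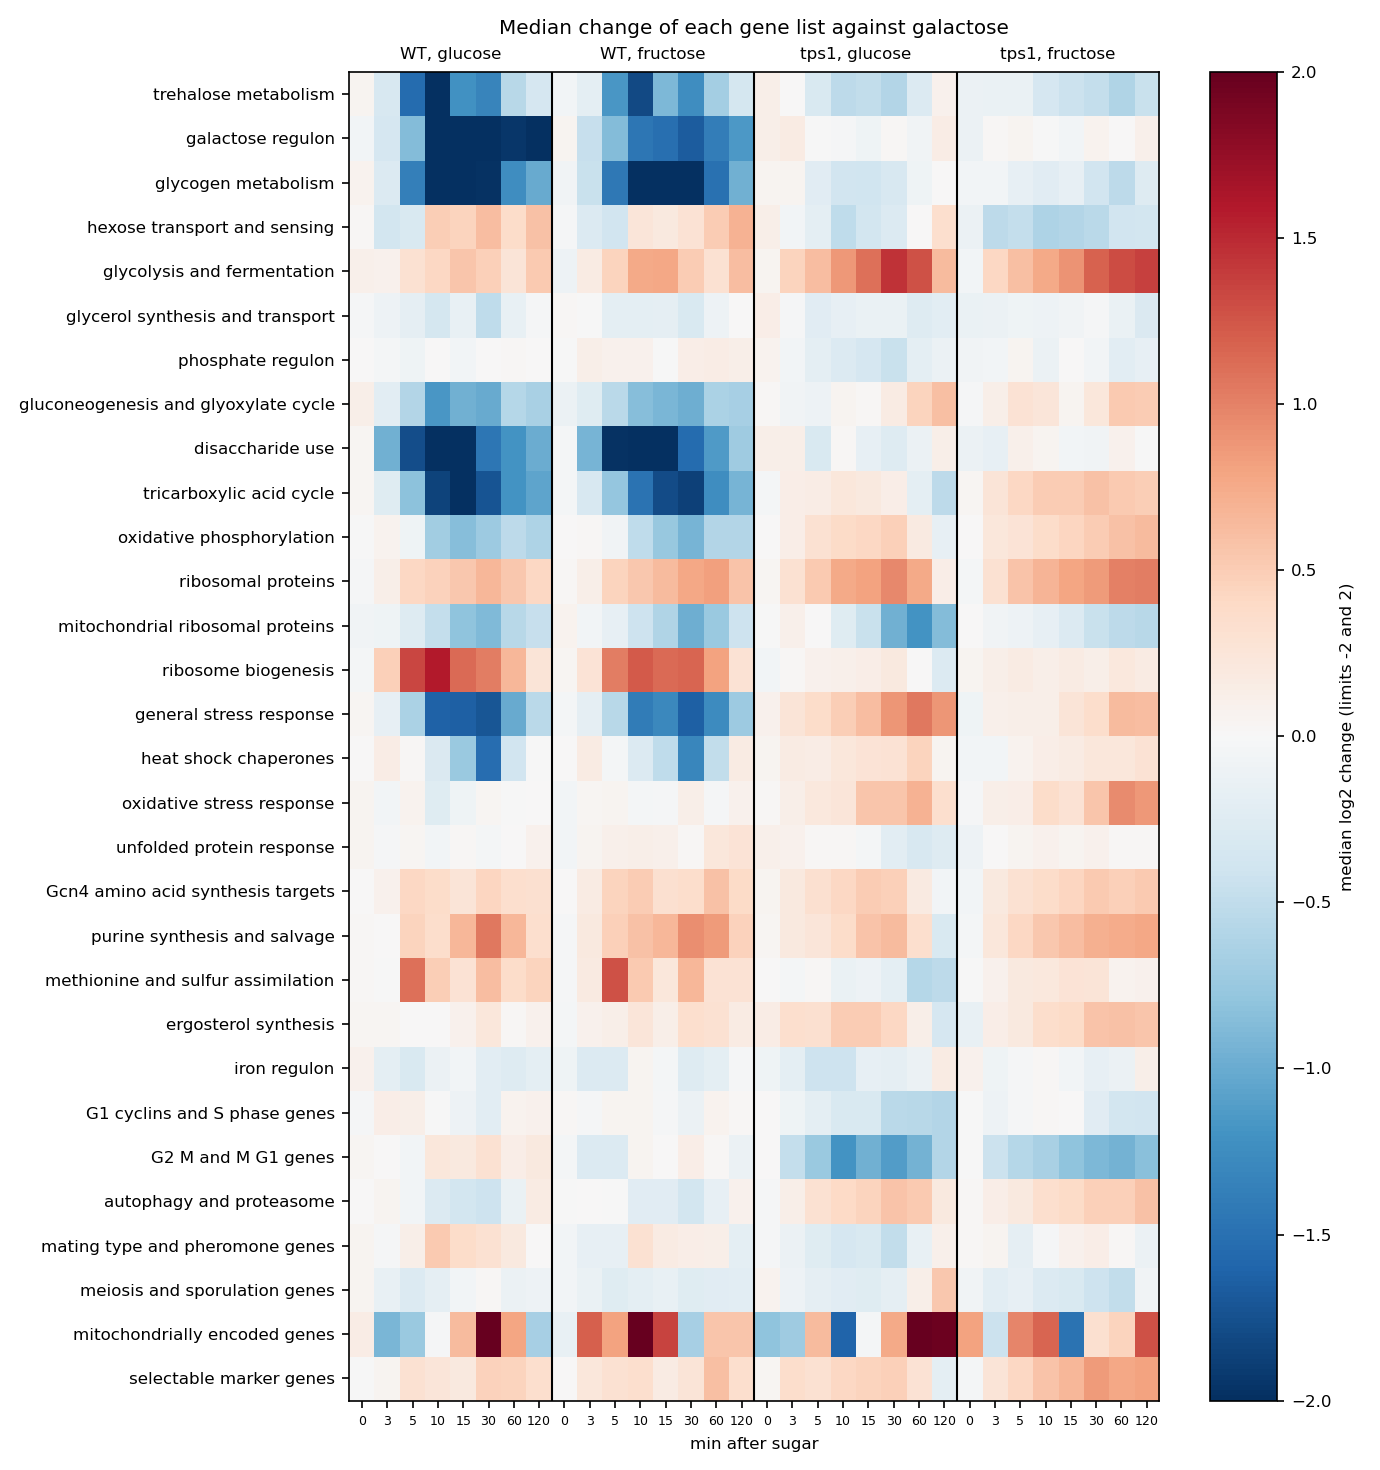
Colour gives the median log2 change of each fixed gene list against the strain's galactose libraries (limits -2 and 2), with lists down the vertical axis and the 8 times (min after sugar) of the 4 courses along the horizontal axis. Ribosome biogenesis reaches its deepest red in WT and stays pale in tps1, and the cell cycle list of G2 to M and M to G1 genes is blue in tps1, while the red of ribosomal protein genes in late tps1 glucose (median 0.63) turns to -0.15 with equal FPKM sums, and the mitochondrially encoded list has 2 measured genes and was not tested.

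The question behind the next comparisons is how the strains differed at the same time after the same sugar, tested on tps1 minus WT differences at matched times. In early glucose 819 genes differed, 319 higher and 500 lower in tps1. TMA10 was at 624.9 ± 227.2 FPKM in tps1 (n = 4) and 20.5 ± 27.9 FPKM in WT (n = 4), a difference of 5.60 ± 0.55 (adjusted p = 6.91e-06). The hexokinase gene HXK1 differed by 5.12 ± 1.02. In the galactose regulon 7 of 9 genes were higher (camera adjusted p = 9.63e-06, and adjusted p = 0.405 with an estimated correlation), among them GAL2 (3.78 ± 0.46) and GAL10 (2.31 ± 0.30). Disaccharide genes were higher in 7 of 8 cases (0.000145, and adjusted p = 0.405 with an estimated correlation), including SUC2, at 267.3 ± 28.8 against 40.2 ± 17.0 FPKM (2.78 ± 0.28, adjusted p = 9.78e-06), and MAL31 (2.6 ± 0.26). Tricarboxylic acid cycle genes were higher in 12 of 15 cases (6.85e-05, and adjusted p = 0.543 with an estimated correlation). Genes for making ribosomes were lower in 16 of 43 cases (1.29e-10, and adjusted p = 0.543 with an estimated correlation). NSR1 was at 158.7 ± 21.2 against 563.0 ± 187.8 FPKM (-1.77 ± 0.20, adjusted p = 1.81e-05), and NOG1 was lower as well (-2.04 ± 0.27). TPO2 (-5.61 ± 0.36), FMP48 (-4.99 ± 0.35) and PFK27 (-2.48 ± 0.19), for the kinase that makes fructose-2,6-bisphosphate, were lower in tps1. Of the 18 G2 to M and M to G1 genes 8 were lower (5.23e-06, and adjusted p = 0.518 with an estimated correlation), among them SCW11 (-2.71 ± 0.25) and CLB1 (-2.31 ± 0.16). Iron regulon genes were lower in 6 of 20 cases (6.85e-05, and adjusted p = 0.405 with an estimated correlation), with a median of -0.81 against -0.47 already in galactose. With adjustment over the list alone, the counts were the same, 7, 7, 12, 16, 8 and 6. Relative to the strain difference in galactose 484 genes were called (138 higher, 346 lower), and equal FPKM sums gave 1067 (166 higher, 901 lower).

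By the late glucose phase 1340 genes differed between the strains, 683 higher and 657 lower in tps1. GAL1, the galactokinase gene, was at 28369.6 ± 5998.5 FPKM in tps1 (n = 3) and 1567.6 ± 396.2 FPKM in WT (n = 3), a difference of 4.19 ± 0.51 (adjusted p = 1.76e-05). GAL10 (3.79 ± 0.35) and GCY1 (4.19 ± 0.38) were alike, and 7 of 9 galactose regulon genes were higher (camera adjusted p = 4.59e-05, and adjusted p = 0.562 with an estimated correlation). GAL1 lies wholly within a noncoding RNA gene of the same strand. Gluconeogenesis and glyoxylate genes were higher in 12 of 15 cases (1.88e-06, and adjusted p = 0.562 with an estimated correlation). They included the lactate permease gene JEN1, at 173.1 ± 23.1 against 6.13 ± 3.17 FPKM (4.73 ± 0.75, adjusted p = 0.00013), and ADH2 differed by 2.67 ± 0.31. General stress genes were higher in 24 of 34 cases (6.78e-06, and adjusted p = 0.672 with an estimated correlation), and so were heat shock chaperone genes in 11 of 23 (0.0107, and adjusted p = 0.672 with an estimated correlation). The chaperone medians against galactose at 30, 60 and 120 min were -1.53, -0.39 and -0.01 in WT and 0.29, 0.44 and 0.06 in tps1, close together by 120 min. HSP26 differed by 3.60 ± 0.52 (adjusted p = 6.52e-05) and the Hsp90 partner gene AHA1 by 2.29 ± 0.38. HXT1 was at 6.43 ± 2.18 FPKM in tps1 against 433.7 ± 63.2 FPKM in WT (-5.90 ± 1.07, adjusted p = 0.000354), and HXT3 (-4.18 ± 0.68) and MEP2 (-4.07 ± 0.31) were also lower. Ribosome biogenesis genes were lower in 10 of 43 cases (0.00163, and adjusted p = 0.672 with an estimated correlation). Methionine and sulfur genes were lower in 10 of 21 (0.0107, and adjusted p = 0.672 with an estimated correlation), among them the transporter genes SAM3 (-2.08 ± 0.24) and SUL2 (-1.87 ± 0.39). Cell cycle genes of the G2 to M and M to G1 periods were lower in 10 of 18 cases (4.59e-05, and adjusted p = 0.562 with an estimated correlation). CLB2 was at 8.31 ± 1.57 against 52.1 ± 11.0 FPKM (-2.50 ± 0.28). Counts adjusted over the list alone were the same, 7, 12, 24, 11, 10, 10 and 10. The equal-sum scaling gave 1959 calls, 273 higher and 1686 lower.

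**Figure D3:**
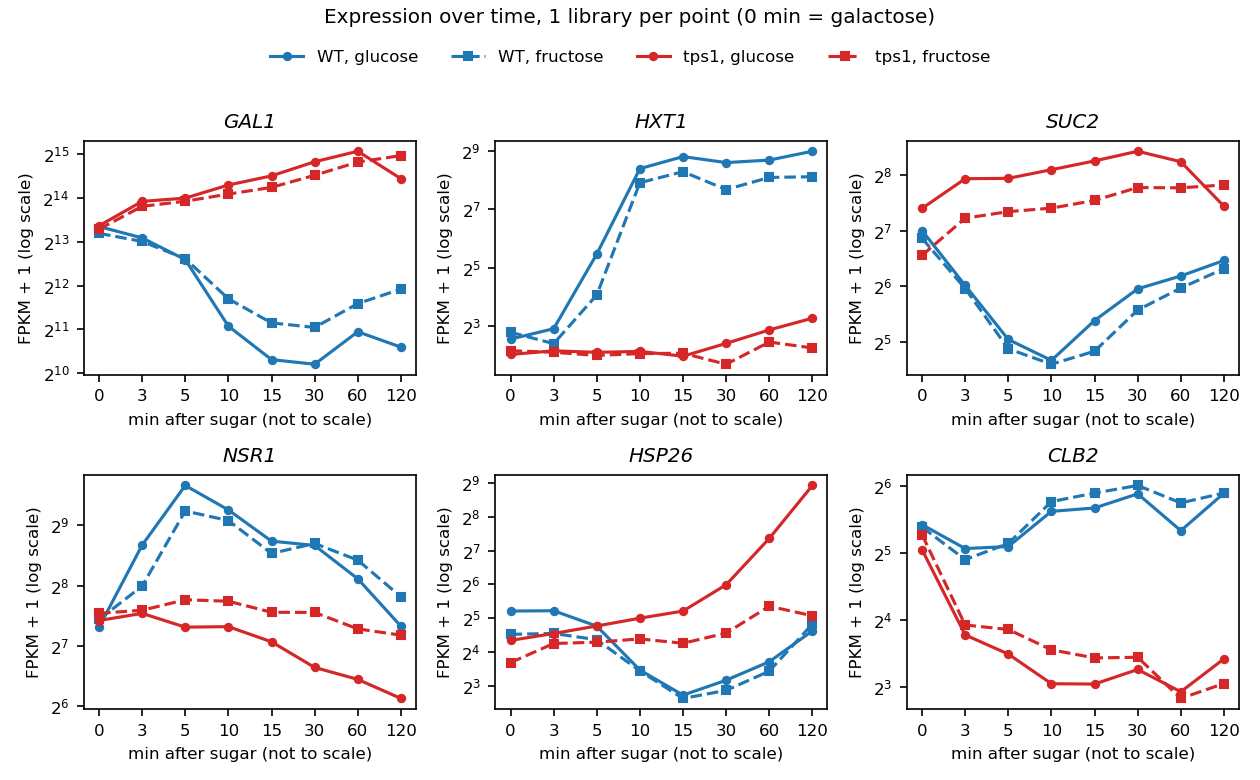
Each point is 1 library, with FPKM + 1 on a log axis against min after sugar (spaced evenly, not to scale), blue for WT and red for tps1, solid for glucose and dashed for fructose. HXT1 climbs in WT (late glucose 433.7 FPKM) and stays low in tps1 (6.43 FPKM), GAL1 and SUC2 fall in WT and not in tps1, NSR1 peaks in WT, CLB2 falls in tps1, and HSP26 reaches 488.5 FPKM in tps1 glucose at 120 min.

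In early fructose 560 genes differed between the strains, 225 higher and 335 lower in tps1. TMA10 (5.40 ± 0.55, adjusted p = 1.12e-05), RGI1 (4.58 ± 0.42) and RGI2 (4.23 ± 0.19) were higher than in WT, and TPO2 (-6.06 ± 0.36, adjusted p = 1.26e-07), YRO2 (-5.94 ± 0.46) and FMP48 (-5.25 ± 0.35) lower. Part of this was present before sugar, since RGI2 differed by 2.59 and YRO2 by -2.23 in galactose. Disaccharide genes were higher in 7 of 8 cases (camera adjusted p = 2.15e-05, and adjusted p = 0.385 with an estimated correlation). SUC2 was at 166.4 ± 15.5 against 35.1 ± 17.6 FPKM (2.32 ± 0.28), and MAL31 was higher too (2.48 ± 0.26). Galactose regulon genes were higher in 6 of 9 cases (6.64e-06, and adjusted p = 0.385 with an estimated correlation), among them GAL2 (3.51 ± 0.46). Tricarboxylic acid cycle genes were higher in 11 of 15 (6.64e-06, and adjusted p = 0.66 with an estimated correlation), and gluconeogenesis and glyoxylate genes in 7 of 15 (3.91e-07, and adjusted p = 0.406 with an estimated correlation). Ribosome biogenesis genes were lower in 5 of 43 cases (6.56e-08, and adjusted p = 0.673 with an estimated correlation), and PFK27 (-2.56 ± 0.19) and CLB1 (-1.99 ± 0.16) were lower too. In tests adjusted over the list alone, the counts were the same, 7, 6, 11, 7 and 5. Relative to the strain difference in galactose the count was 123 (34 higher, 89 lower), and equal FPKM sums gave 678 (153 higher, 525 lower).

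Late in fructose 1206 genes differed between the strains, 598 higher and 608 lower in tps1. Respiratory genes stood out: 19 of 30 genes of oxidative phosphorylation were higher in tps1 (camera adjusted p = 1.97e-08, and adjusted p = 0.607 with an estimated correlation). Among them were ATP2 (1.93 ± 0.31), COR1 (1.87 ± 0.24) and ATP5 (1.80 ± 0.26). So were 13 of 15 genes of the tricarboxylic acid cycle (8.51e-05, and adjusted p = 0.648 with an estimated correlation), such as SDH3 (2.77 ± 0.47), FUM1 (2.31 ± 0.32) and the citrate synthase gene CIT1 (2.22 ± 0.46). Gluconeogenesis and glyoxylate genes were higher in 11 of 15 cases (2.84e-06, and adjusted p = 0.607 with an estimated correlation). JEN1 was at 195.4 ± 4.57 against 8.08 ± 6.55 FPKM (4.73 ± 0.75), and the succinate carrier gene SFC1 was higher too (3.52 ± 0.35). ADH2 was at 450.4 ± 99.7 FPKM against 29.6 ± 6.08 FPKM in WT (3.88 ± 0.31, adjusted p = 1.89e-06). Hexose transport and sensing genes were lower in 7 of 15 cases (0.00486, and adjusted p = 0.607 with an estimated correlation). HXT1 was at 3.5 ± 1.15 against 249.9 ± 40.7 FPKM (-5.82 ± 1.07, adjusted p = 0.000482), and HXT3 (-4.29 ± 0.68), HXT4 (-3.66 ± 0.54) and STD1 (-3.28 ± 0.40) were lower too. GAL1 (3.24 ± 0.51) and GAL10 (2.62 ± 0.35) were higher, with 5 of 9 galactose regulon genes called (0.000523, and adjusted p = 0.607 with an estimated correlation). CLB2 (-2.78 ± 0.28) and PFK27 (-3.28 ± 0.22) were lower, as were 9 of 18 G2 to M and M to G1 genes (0.000523, and adjusted p = 0.607 with an estimated correlation). When adjusted over the list alone, the counts were the same, 19, 13, 11, 7, 5 and 9. Scaled to equal FPKM sums, the libraries gave 1740 calls, 196 higher and 1544 lower, and 4 of 30 oxidative phosphorylation genes higher in place of 19.

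Whether the strain difference itself depended on the sugar was tested as the difference in glucose minus that in fructose. In the early phase limma called 0 genes, with 282 at an unadjusted p under 0.05, and without matching by time it called 2. In the late phase it called 9, 5 higher and 4 lower (1170 at an unadjusted p under 0.05). GRE1 (YPL223C, chromosome XVI, 128632 to 129138) was at 127.8 ± 76.8 FPKM in late tps1 glucose and 21.8 ± 0.645 FPKM in late tps1 fructose, against 12.4 ± 1.63 and 14.7 ± 3.56 FPKM in WT (2.53 ± 0.40, adjusted p = 0.025). PIR3, for a cell wall protein, was at 94.1 ± 41.8 and 28.7 ± 2.78 FPKM in tps1 against 29.7 ± 3.54 and 33.7 ± 6.65 FPKM in WT (1.75 ± 0.28, adjusted p = 0.025). IRA2, for a Ras inhibitor, was at 27.7 ± 9.31 and 9.92 ± 1.19 FPKM in tps1 against 6.7 ± 0.538 and 6.99 ± 0.488 FPKM in WT (1.4 ± 0.25, adjusted p = 0.0271). OST5 (1.36 ± 0.24) and CDC39 (1.13 ± 0.20) were the other higher calls, and YER078W-A, YDR455C, MRX15 and FUN26 the lower ones. With 2 of the 3 late times left, limma called 0 genes without 60 min or without 120 min, and 73 without 30 min. The estimates moved little: GRE1 was at 2.53 without 60 min (adjusted p = 0.349) and 2.37 without 120 min (adjusted p = 0.0797), PIR3 at 1.53 and 1.77, and IRA2 at 1.23 and 1.27. The equal-sum scaling gave 4 calls, leaving out genes under 300 bp or unmatched gave 19, and no matching by time gave 44. Mitochondrial ribosomal protein genes had a late median of -0.45 with 0 of 56 called, and 3 lower adjusted over the list alone (camera adjusted p = 3.11e-09, and adjusted p = 0.962 with an estimated correlation).

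How the sugars differed within a strain was tested on glucose minus fructose differences at matched times. These were not taken relative to the difference at 0 min. With 1 culture per course, a difference between cultures cannot be told apart from one between sugars. In WT 8 genes differed early, 1 higher and 7 lower in glucose, and 11 late, 1 higher and 10 lower. Of these, 5 of 8 and 6 of 11 were under 300 bp or unmatched, a class that varied more between galactose libraries. HOR7, a stress-related gene of 180 bp, was lower in glucose in both phases, at 2497.7 ± 787.6 against 6504.2 ± 2250.2 FPKM early (-1.37 ± 0.23, adjusted p = 0.0139) and 1840.4 ± 628.4 against 5297.2 ± 1090.4 FPKM late (-1.56 ± 0.27, adjusted p = 0.0142, and 0.145, 0.123 and 0.121 without 30, 60 and 120 min). GCY1 was lower late in glucose (-1.08 ± 0.17, adjusted p = 0.0116). So were the ribosomal protein genes RPL43B, RPS29A and RPS21A, 3 of 138 (camera adjusted p = 2.12e-13, and adjusted p = 0.665 with an estimated correlation, 3 adjusted over the list alone). At least RPS29A is under 300 bp and belongs to the class that varied more. With a time left out, the early count was 0 without 10 min, 1 without 5 min or 15 min and 27 without 3 min, and the late count was 0 without 30 min or 60 min and 2 without 120 min. HOR7 kept late estimates of -1.45, -1.59 and -1.66 without 30, 60 and 120 min. Without matching by time the counts were 1 and 0, without genes under 300 bp or unmatched 3 and 6, and a pseudocount of 5 gave 4 early. Scaled to equal FPKM sums, the libraries gave 8 early (3 higher, 5 lower) and 14 late (5 higher, 9 lower).

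In tps1 12 genes differed between the sugars early, 4 higher and 8 lower in glucose. ZEO1 (-1.5 ± 0.19, adjusted p = 0.00362), ADH2 (-1.39 ± 0.18, adjusted p = 0.00362) and MIG1 (-1.09 ± 0.15, adjusted p = 0.00362) were lower in glucose. The tps1 galactose libraries already differed in ADH2, as the SD of its galactose level above shows. Neither its early nor its late difference can therefore be assigned to the sugar. Without 15 min the count was 0, with adjusted p = 0.054 for ZEO1, ADH2 and MIG1. It was 3 without 5 min, 6 without 10 min, 24 without 3 min and 3 without matching by time. Late, 206 genes differed, 133 higher and 73 lower in glucose. Stress genes were higher in glucose, 7 of 34 (camera adjusted p = 0.000799, and adjusted p = 0.62 with an estimated correlation). HSP26 was at 238.3 ± 222.5 against 31.7 ± 8.7 FPKM (2.44 ± 0.30, adjusted p = 7.47e-05) and GRE1 and the osmotic stress gene SIP18 differed by 2.33 ± 0.23 and 2.46 ± 0.48. The transporter gene HXT2 was at 34.2 ± 22.1 against 8.57 ± 1.64 FPKM (1.69 ± 0.25, adjusted p = 0.00021), with 3 of 15 transport and sensing genes higher (0.000321, and adjusted p = 0.62 with an estimated correlation). ADH2 (-1.30 ± 0.20, adjusted p = 0.000298) and RPS6B (-1.44 ± 0.14, adjusted p = 2.25e-05) were lower in glucose. The same held for 3 of 15 tricarboxylic acid cycle genes (1.74e-06, and adjusted p = 0.62 with an estimated correlation) and 4 of 30 oxidative phosphorylation genes (3.02e-05, and adjusted p = 0.643 with an estimated correlation), counts of 0 with equal FPKM sums. Counts adjusted over the list alone were the same, 7, 3, 3 and 4. The late count was 400 without 30 min (264 higher, 136 lower) and 192 without 60 min (125 higher, 67 lower). Without 120 min it was 149 (75 higher, 74 lower), so the excess of genes higher in glucose was not seen without that time. The tps1 glucose library at 120 min held 34.9% of its FPKM sum in its 10 highest genes, with 11.08% in RPL41B alone. Leaving out genes under 300 bp or unmatched gave 128, a pseudocount of 5 gave 104, and equal FPKM sums gave 206 (171 higher, 35 lower).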

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

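The comparisons, also those relative to galactose or with a time left out, were fixed before the data were examined. The test of gene length and that of GC content were written before their results were seen. The other tests of explanations in this part were chosen after the result was seen.

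The strain difference depended on the sugar at 0 genes in the early phase and at 9 in the late phase, by a direct test of the difference of differences. Higher in glucose were GRE1 (2.53), PIR3 (1.75), IRA2 (1.4), OST5 (1.36) and CDC39 (1.13). Lower were YER078W-A (-5.78), YDR455C (-1.55), MRX15 (-1.17) and FUN26 (-1). The estimate for YER078W-A depends on the pseudocount, since the gene was listed at 0 in most groups. The 9 calls came with 2 of 64 label swaps at matched times giving as many genes, the real labels included, and the other swap with 9 exchanges all late labels together and is equal by construction. The next highest swap gave 8, and 2 of 64 is the lowest share this test can give. Without 60 min or without 120 min 0 genes were called, so chance labelling is not excluded for these 9.

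Between phases and galactose the strain difference also changed, by a test of each phase against the difference at 0 min. This called 484 genes in early and 1017 in late glucose, and 123 in early and 928 in late fructose. For the strain differences themselves, 2 of 64 label swaps gave as many genes in either phase in each sugar, the real labels and their equal by construction: 1613 in glucose (highest other 1613, next 1344, median 0) and 1340 in fructose (highest other 1340, next 1158, median 0). The real labels thus gave the highest counts, and 2 of 64 is the lowest share this test can give. For glucose minus fructose the counts were 16 in WT (highest other 16, next 12, median 0) and 211 in tps1 (highest other 211, next 203, median 6), again 2 of 64 each. None of these swaps speaks to variation between cultures.

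An entry without a gene ID held a signal of up to 12.95 FPKM in the deposited table, outside the comparisons.

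The FPKM sum of tps1 rose after sugar while the median gene stayed level: late sums were 1.82 and 1.92 times those in galactose in glucose and fructose, against 1.11 and 1.17 in WT. The rise was not carried by a few genes, since without the 10 highest genes of each library the ratios were 1.58 and 1.80. GC content did not account for the whole slope of the late change on abundance, which kept 0.91 and 0.90 of its size with GC content in the model. That slope was small in glucose (0.054, against 0.145 in fructose), and the test does not speak to the sum itself. The late change had a Spearman correlation with GC content of 0.06 and 0.27 in tps1 glucose and fructose, against -0.1 and -0.09 in WT. Gene length bias or broken RNA could not be excluded, since the same ratio of slopes with length was 0.69 in glucose and 0.90 in fructose. The late change also had a Spearman correlation with gene length of -0.21 and -0.3 in tps1 glucose and fructose, against 0.04 and 0.01 in WT. Its correlation with abundance in galactose was 0.11 and 0.4 in tps1, weaker than that with length in glucose. A biological explanation, in which abundant messenger RNAs of tps1 cells gain relative to the rest, is consistent with a median change of 0.48 and 0.86 in the most abundant 10% of genes against 0.11 and -0.12 in the least abundant 10%, but it was not tested apart from the authors' scaling.

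In the tps1 glucose course 130 genes of at least 300 bp rose and 47 fell at least 2-fold from 60 to 120 min, against 31 and 23 in WT. The 10 highest genes of the 120 min library held 34.9% of its FPKM sum, against 13.2 to 24.1% in the other libraries. RPL41B alone held 11.08% of that sum, so the share rests in part on 1 gene. This gene also held 9.82% in the WT fructose course at 0 min, before sugar. Of genes that moved and at 60 min lay at least 2-fold from the WT level at 120 min, 78 went towards it, by a median of 82.9% of the way, and 11 away, a direction favoured by choosing genes on the 60 min library. WT cells or RNA mixed into that library might give such a shift, but TPS1 argues against it: it went from 1.18 FPKM at 60 min to 0.26 FPKM at 120 min, 0.098% of the 264.2 FPKM in the WT library. A change of the cells themselves, such as part of the culture adapting to glucose, stays open and was not tested, because the time has 1 library.

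Short genes differed between the galactose libraries of a strain, which should be alike. In WT 23 of 204 genes under 300 bp (11.3%) were at least 2-fold apart, against 31 of 5522 longer genes (0.56%), and in tps1 31 of 204 (15.2%) against 28 (0.51%). The ratios of these shares were 20.1 and 30.0 (Fisher's exact p = 5.89e-20 and 2.99e-30). These ratios describe the pattern and cannot decide its source: gene length near or under that of a sequenced fragment stays open, and no biological explanation was tested. Calls of short genes are the less certain for it.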

How the results depend on the processing

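Equal FPKM sums, leaving out genes under 300 bp or unmatched, and the other course's galactose library as baseline were chosen after the result was seen, and the other settings before the data were examined. Strain and sugar differences were paired by time, and the labels name no replicate cultures to pair. Unless stated otherwise, the cause was not tested.

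With equal FPKM sums, counts moved to 449 in late WT fructose, 905 and 2261 in early and late tps1 glucose, 694 and 2566 in early and late tps1 fructose, and 4 for the late dependence of the strain difference on sugar. By construction this scaling divides every FPKM value of a library by the same factor, and genes near or below the pseudocount shift less on the log2 scale. Median-of-ratios scaling, a pseudocount of 0.1 and a fit without trend left every count within 1.5 times. As deposited, the median gene already lay between -0.05 and 0.02 in every comparison. Median-of-ratios scaling could therefore hardly move a count, and it is no check on the authors' scaling. A pseudocount of 5 gave 136 in early tps1 glucose, 116 in early tps1 fructose, 4 in early glucose minus fructose of WT and 104 in late glucose minus fructose of tps1. Without a filter the galactose comparison gave 3. Without genes under 300 bp or unmatched it gave 37, the late dependence on sugar 19, early and late glucose minus fructose of WT 3 and 6, and the late one of tps1 128.

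With the same course's galactose library alone as baseline, counts were 227 and 23 in early and late WT glucose, 66 and 20 in early and late WT fructose, 138 in early tps1 glucose and 30 in early tps1 fructose. With the other course's library alone they were 77 and 28, 76 and 17, and 105 in early tps1 glucose. A baseline of 1 library leaves fewer samples, and that library is assumed to vary like the other groups. Without matching by time, the dependence on sugar gave 2 early and 44 late, early and late glucose minus fructose of WT 1 and 0, and the early one of tps1 3. Galactose differences tested with the spread of the 16 matched differences gave 3. Relative to the difference in galactose, early strain differences gave 484 in glucose and 123 in fructose.

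Leaving out 1 library or time gave 3 to 10 for the galactose comparison, where a strain then has 1 library assumed to vary like the other, 261 to 627 and 61 to 151 for early and late WT glucose, 185 to 529 and 94 to 461 for WT fructose, 127 to 364 and 779 to 1205 for tps1 glucose, and 122 to 304 and 924 to 1149 for tps1 fructose. The strain differences gave 616 to 1156 and 1182 to 1518 in early and late glucose, and 445 to 768 and 1103 to 1224 in fructose. The late dependence on sugar gave 0 to 73, early and late glucose minus fructose of WT 0 to 27 and 0 to 2, and those of tps1 0 to 24 and 149 to 400. The times behind the extremes were 60 or 120 min (0) and 30 min (73) for the dependence on sugar, 10 min (0) and 3 min (27) for early WT, 30 or 60 min (0) for late WT, and 15 min (0) and 3 min (24) for early tps1.

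The tests of gene lists depended most on their correlation. At the preset correlation, 12 lists passed in galactose, 15, 20, 15 and 18 in early and late WT glucose and fructose, 12, 9, 8 and 9 in tps1 likewise, 16, 13, 12 and 15 in the strain differences, 10 and 7 in their dependence on sugar, and 14, 7, 9 and 12 in glucose minus fructose of WT and of tps1. With an estimated correlation 1 list passed in late WT glucose (the galactose regulon, adjusted p = 0.0353) and 0 in every other comparison. With fry the numbers moved to 0 in galactose, 8 in early WT glucose, 14 in late tps1 fructose, 0 and 0 for the dependence on sugar, 1 and 1 for WT and 2 for early tps1 in glucose minus fructose.

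Among named genes, 5 values reversed, all relative to the strain difference in galactose: TPS1, at 1.31 and 0.92 in early and late glucose and 0.98 and 0.81 in fructose, and ADH2, at -0.07 in early glucose. For TPS1 the construction shows the cause, since the WT level fell and the tps1 level was near 0 throughout. Of 1140 values each, 1114 stayed on their side of the threshold with a pseudocount of 0.1, 1078 with one of 5, 1122 without a filter, 1135 with median-of-ratios scaling, 1129 without trend and 960 with equal FPKM sums. Leaving out 1 library or time kept 3494 of 3974. A single galactose library as baseline kept 342 of 545 (same course) or 348 of 545 (other course). No matching by time kept 531 of 559, leaving out genes under 300 bp or unmatched 1024 of 1028, the spread of the 16 matched differences 31 of 36, and values relative to galactose 199 of 319.

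Depth limits statements on rare messengers: 1 fragment over 1 kb equals 0.0876 to 0.3326 FPKM, so a gene listed at 0 is not shown to be absent below that.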

Other observations

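All counts in this part were chosen after the result was seen, except the tests of gene lists, which were fixed before the data were examined.

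Relative to the median gene, the genes that glucose moved in WT moved little in tps1. They were chosen by their calls in WT, which favours large medians in WT. The medians in tps1 also depend on scaling, since equal FPKM sums moved the median gene to -0.49 and -0.46 in early tps1 glucose and fructose. Of 241 genes that rose in early WT glucose 0 were called higher in tps1 (limma, 1.0 if the calls were independent) and 10 were called lower, with a median change of 0.00 in tps1 against 1.24 in WT. Of 196 that fell, 19 were called lower in tps1 (6.4 if independent) and 1 higher, with a median of -0.11 against -1.60. In early fructose 7 of 150 rises and 16 of 164 falls were shared (1.0 and 3.9 if independent), with medians of 0.12 against 1.21 and -0.24 against -1.74, and 5 and 0 were called the other way. By late fructose 43 of 94 WT rises were shared (7.0 if independent), with a median of 0.98 in tps1 against 1.25 in WT, and 29 of 152 falls (13.3 if independent), with medians of -0.24 and -1.54. Called the other way were 4 of the rises and 12 of the falls. With equal FPKM sums just 45 genes rose in late WT fructose and 22 in late tps1 fructose, so at most 22 rises could be shared. How many were shared under that scaling was not counted. In late glucose 5 of 28 rises and 7 of 80 falls were shared (2.1 and 6.3 if independent), and 2 and 4 were called the other way. Whether the sharing differed between sugars was not tested.

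Other lists gave mixed results between the strains. Autophagy and proteasome genes were higher in tps1 in late glucose, 6 of 20 (camera adjusted p = 0.0294, and adjusted p = 0.672 with an estimated correlation), including the proteasome subunit genes PRE2 (1.88 ± 0.20) and PUP2, though with equal FPKM sums their median was -0.04. Against galactose the medians at 30, 60 and 120 min were -0.42, -0.14 and 0.16 in WT and 0.57, 0.52 and 0.19 in tps1, close together by 120 min. Mating type and pheromone genes were lower in tps1 in early glucose, 5 of 16 (0.0223, and adjusted p = 0.543 with an estimated correlation). In late fructose 3 of 13 unfolded protein response genes were lower in tps1, a list whose test gave an adjusted p of 0.357, and phosphate regulon genes were called in both directions, 1 higher and 2 lower of 19 (0.0405, and adjusted p = 0.607 with an estimated correlation). Between sugars, 1 of 17 meiosis and sporulation genes was higher in late tps1 glucose than fructose (0.00862, and adjusted p = 0.62 with an estimated correlation).

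Changes between neighbouring times were counted in each course. From 0 to 3 min 90 genes of at least 300 bp rose at least 2-fold in WT glucose and 91 in WT fructose, against 9 and 10 in tps1, while 64, 78, 76 and 68 fell in the same order. From 5 to 10 min 158 genes fell in WT glucose and 32 in tps1 glucose. From 30 to 60 min 82 and 65 genes rose in WT glucose and fructose, and 73 and 42 in tps1. These are counts between single libraries and were not tested.

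The galactose libraries of a strain differed by a median of 0.12 (WT) and 0.14 (tps1) on the log2 scale, and 102 of 6203 genes were at least 2-fold apart in each strain.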
